A study of Mus musculus with 15 samples.

How the data were processed

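Values of 15 Affymetrix mouse expression arrays were used, 5 each from SVZ, hippocampus and cerebellum, as grouped by the sample titles and tissue labels. Per the labels' protocols, sorted cells of 10 to 12 mice were pooled for each array, RNA was purified with Trizol and RNeasy Micro columns, amplified with the WT-Ovation Pico system and biotin labelled. The deposited values were normalized by the authors with RMA, per the submitters' processing notes, and were read here as log2 signal, since the notes name no log base and the array maxima lay between 14.97 and 15.08. The version of RMA and the dates of the scans are not given in the sources used here. No detection calls came with the values, so no probe set was left out as absent, and precision is limited by the number of arrays and, for dim genes, by the background. 1 value was below 0, and the values were used as deposited, with no floor.

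Of 45101 probe sets, 34958 carried 1 gene symbol in the platform annotation, 932 carried several, and 9211 were not listed. Symbols were updated through Entrez identifiers for 34754 probe sets, and 204 were not matched and kept the symbol of the annotation. The 64 control probe sets were left out of the tests, 12 of which detect poly-A spike-in RNA and gave a measure per array. For each of 18194 genes the probe set with the highest mean over the 15 arrays was used, and 9012 genes had several. Among genes called in SVZ against cerebellum, 631 had further probe sets, 1208 in number, of which 954 had the same sign and 304 were called in the same direction, and 1 gene had probe sets called both ways. In hippocampus against cerebellum 552 genes had 1093 further probe sets, 885 with the same sign and 287 called in the same direction. In SVZ against hippocampus the 4 genes called had 6 further probe sets, 4 with the same sign and 0 called in the same direction.

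The design, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where a choice is said to have been made after. limma 3.58.1 in R 4.3.3, with the data.table package at version 1.17.8, fitted region over all 15 arrays, which share one estimate of the spread, and gave the 3 comparisons. p values were adjusted by the Benjamini-Hochberg method over all genes, and a gene was called at an adjusted p under 0.05. Genes common to both stem cell regions followed the thresholds of the series design, more than 4-fold at an unadjusted p under 0.01 against cerebellum. Genes at a high level were those in the top 10% by region mean. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

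Shifts of 29 fixed lists were tested with camera at a preset correlation of 0.01, and the 87 tests were adjusted together. The lists covered the Shh, Notch, BMP, Wnt and FGF and EGF pathways, astrocyte core genes, neural stem cell and radial glia genes, Bergmann glia and cerebellar astrocyte genes, forebrain transcription factors, and midbrain and hindbrain transcription factors. Further lists held transit amplifying cell and neuroblast genes, cell cycle genes, glutamate and GABA transport and receptors, potassium channels, extracellular matrix, cholesterol and lipid synthesis, reactive astrocytes, and immediate early and dissociation genes. Markers were listed for neurons in general, for cerebellar, hippocampal and striatal neurons, and for ependymal cells, choroid plexus, oligodendrocytes, oligodendrocyte precursors, microglia, endothelial cells and pericytes, and red blood cells. Some genes stand on more than one list. Named genes were, per comparison, the 10 largest positive and the 10 largest negative differences among called genes whose arrays did not overlap, the sort genes with measured Shh pathway members, and per list the 2 largest called differences each way, or the 2 smallest p values where none was called. For common genes and genes at a high level the 10 with the largest smaller difference were named in each direction tested.

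The alternatives were the replicate number as a block, quantile normalization, median centring, leaving out dim probe sets, the mean of a gene's probe sets, every probe set on its own, array weights, a trended and robust spread, only the groups compared, other thresholds, an estimated correlation for the lists, split cerebellum arrays, and leaving out each array in turn. Settings added after seeing the data left out SVZ 1 with hippocampus 3, left out cerebellum 4 with cerebellum 5, or entered the mean spike-in level of each array as a covariate. The fit was tested in 5 simulations with 250 changed genes per size in all, with recovery given for one shared spread. For SVZ against cerebellum it recovered 3.2% of genes changed by a log2 difference of 1, 37.2% at 2, 66.0% at 3 and 85.6% at 4, with 4.57% of calls false where all regions shared one spread and 18.7% where each kept its own. For hippocampus against cerebellum the shares recovered were 3.2%, 31.6%, 61.2% and 82.0%, with 5.32% and 16.4% of calls false. For SVZ against hippocampus they were 4.0%, 31.2%, 64.0% and 82.0%, with 5.62% and 31.3% of calls false. The list test called 5 of 5 shifted and 1 of 5 unshifted lists.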

Results

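The arrays measured gene expression in astroglia of the adult mouse brain that had responded to Sonic hedgehog (Shh), a secreted signal that activates the transcription factor Gli1. Male mice aged 6 to 8 weeks carried an inducible recombinase under Gli1 control, a red reporter that it switches on permanently, and a green reporter under the astroglial promoter of Gfap. Tamoxifen was given as 2 doses of 10 mg, and 3 weeks later cells positive for both reporters were sorted from the subventricular zone (SVZ), the hippocampus and the cerebellum. The SVZ and the hippocampus hold the adult neural stem cells, whereas the cerebellum served as the region of comparison. Stem cell presence goes with brain region here (forebrain against cerebellum), so comparisons with cerebellum cannot tell them apart. Each region had 5 arrays, and each array carried amplified RNA pooled from 10 to 12 mice. The array medians lay between 1.12 and 1.31 on the log2 scale, which is low for RMA values. Whether a further background or scaling step was applied is not given in the sources used here, and such a step would alter the size of every log2 difference. The number of arrays limits the precision of every value. The cerebellum arrays resembled each other more closely, with pairwise correlations across genes of 0.939 to 0.97, than the SVZ arrays (0.763 to 0.894) or the hippocampus arrays (0.792 to 0.884). Over the 4817 genes with a mean level above 3, the median SD between arrays was 1.00 in SVZ, 1.00 in hippocampus and 0.481 in cerebellum. With each region's own spread, 16.4% to 31.3% of simulated calls were false, which depends on how many genes change. SVZ-hippocampus had 238 false calls in 5 simulations but 4 calls in the data, so adjusted p under 0.05 is lenient. Poly-A spike-in probe sets read 12.56 ± 0.85 in SVZ, 12.46 ± 0.55 in hippocampus and 10.28 ± 1.6 in cerebellum (log2, mean ± SD, n = 5 arrays each). Differences below are given on the log2 scale with the standard error of the limma fit, each from 5 against 5 arrays, and genes near the background in 1 region have understated folds and no firm order by size.

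**Figure D1:**
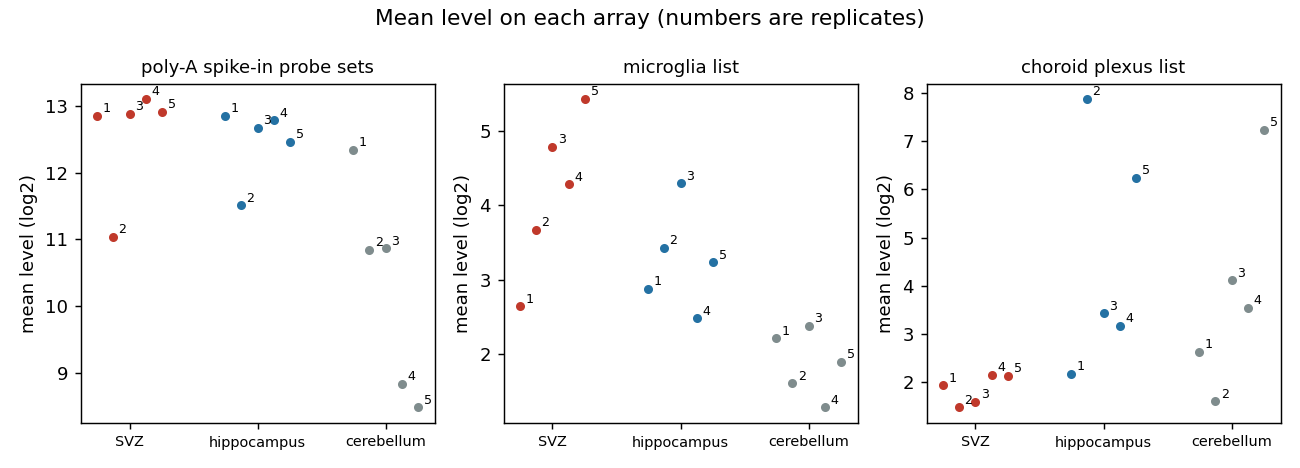
Mean level (log2, y axis) on each array of the poly-A spike-in probe sets, the microglia list and the choroid plexus list in SVZ, hippocampus and cerebellum, with the replicate number beside each point. The spike-in level is 12.34 in cerebellum 1 and 8.49 in cerebellum 5, and the choroid plexus mean is 7.87 in hippocampus 2.

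The genes that defined the sort were compared first. Gli1, the transcriptional target of Shh used to label the cells, read 2.80 ± 1.31 in SVZ, 2.83 ± 1.91 in hippocampus and 3.17 ± 0.35 in cerebellum (mean ± SD, n = 5). Its adjusted p was 0.807 for SVZ against cerebellum, 0.819 for hippocampus against cerebellum and 0.994 for SVZ against hippocampus. Gfap, the astroglial intermediate filament gene behind the green reporter, read 4.51 ± 1.06, 6.93 ± 0.63 and 4.99 ± 1.23 in the same order, with adjusted p values of 0.657, 0.0843 and 0.364. Ptch1, the Shh receptor and itself a target of the pathway, was lower than in cerebellum by a log2 difference of -1.66 ± 0.42 in SVZ (adjusted p = 0.0339) and -1.82 ± 0.42 in hippocampus (adjusted p = 0.0231). Gas1, a co-receptor for Shh, was lower by -2.43 ± 0.57 in SVZ (adjusted p = 0.0236) and -2.24 ± 0.57 in hippocampus (adjusted p = 0.0390). Without cerebellum 4 the adjusted p of Ptch1 was 0.0866 in SVZ and 0.0649 in hippocampus, and that of Gas1 was 0.0653 and 0.102. Cdon, another co-receptor, was higher in hippocampus by 0.90 ± 0.23 (adjusted p = 0.0393), and this p rose to 0.0928 without cerebellum 2. With quantile normalization of the arrays none of these 5 Ptch1, Gas1 and Cdon differences passed, at -1.32 and -1.47 for Ptch1 (adjusted p = 0.142 and 0.112), -2.04 and -1.81 for Gas1 (0.0942 and 0.168) and 0.83 for Cdon (0.125). The Cdon adjusted p was 0.0671 with median centring. With the mean of a gene's probe sets Ptch1 stood at -0.65 in SVZ (adjusted p = 0.175) and -1.17 in hippocampus (adjusted p = 0.0214), and Cdon at 0.50 (adjusted p = 0.0758).

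Gli2, Gli3, Smo and Hhip did not pass in either region. Against cerebellum, Gli2 differed by 1.6 ± 0.67 in SVZ (adjusted p = 0.193) and by 2.24 ± 0.67 in hippocampus (adjusted p = 0.0769), and Gli3 by 1.45 ± 0.68 (adjusted p = 0.238) and 0.29 ± 0.68 (adjusted p = 0.823). Smo, the signal transducer, differed by -0.37 ± 1.27 in SVZ (adjusted p = 0.885) and 0.40 ± 1.27 in hippocampus (adjusted p = 0.872). Hhip, a Shh-binding inhibitor, differed by -0.05 ± 0.35 (adjusted p = 0.948) and -0.19 ± 0.35 (adjusted p = 0.772). Of the 17 measured genes of the Shh list, 2 were lower and 15 did not pass in SVZ, and 1 was higher, 2 were lower and 14 did not pass in hippocampus. Adjusted over the list alone, the counts were 2 lower in SVZ, and 2 higher and 2 lower in hippocampus. The list as a group did not pass, with camera adjusted p values of 0.898 in SVZ and 0.939 in hippocampus, and its mean was below 0 (-0.035 and -0.017) where its median (0.010 and 0.112) and the test pointed up.

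SVZ astroglia, of a region with stem cells, were compared with cerebellar astroglia. They carried 57.5 times as much signal for Nr2e1, a nuclear receptor that maintains adult neural stem cells, with a log2 difference of 5.85 ± 0.81 (adjusted p = 0.000662). Higher as well were the cell adhesion gene Cadm1 (5.46 ± 0.47, adjusted p = 9.35e-06) and the glypican gene Gpc5 (5.32 ± 0.52, adjusted p = 3.39e-05). So were Astn1, which encodes the adhesion protein astrotactin (5.17 ± 0.57, adjusted p = 9.28e-05) and the Wnt receptor gene Fzd2 (5.13 ± 0.42, adjusted p = 5.63e-06). Mki67, a gene of dividing cells, was 26.8-fold higher at 4.74 ± 0.75 (adjusted p = 0.00189), and the noncoding RNA Miat was 39.6-fold higher at 5.31 ± 0.89 (adjusted p = 0.00284). Among the lower genes were Gria4, an AMPA-type glutamate receptor subunit (-7.26 ± 0.69, adjusted p = 2.45e-05), Mybpc1, a myosin-binding protein gene (-6.10 ± 0.37, adjusted p = 3.65e-07), and the glutamine transporter gene Slc38a1 (-5.90 ± 0.85, adjusted p = 0.000966). So were the protease inhibitor gene A2m (-5.57 ± 0.62, adjusted p = 0.000111) and the growth factor gene Gdf10 (-5.40 ± 0.63, adjusted p = 0.000163). On the SVZ arrays Gria4 read 0.99 to 5.47 and Mybpc1 0.58 to 2.94, in part near the array medians. By the rule used to name them, each of these genes had all 5 SVZ arrays on one side of all 5 cerebellum arrays.

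**Figure D2:**
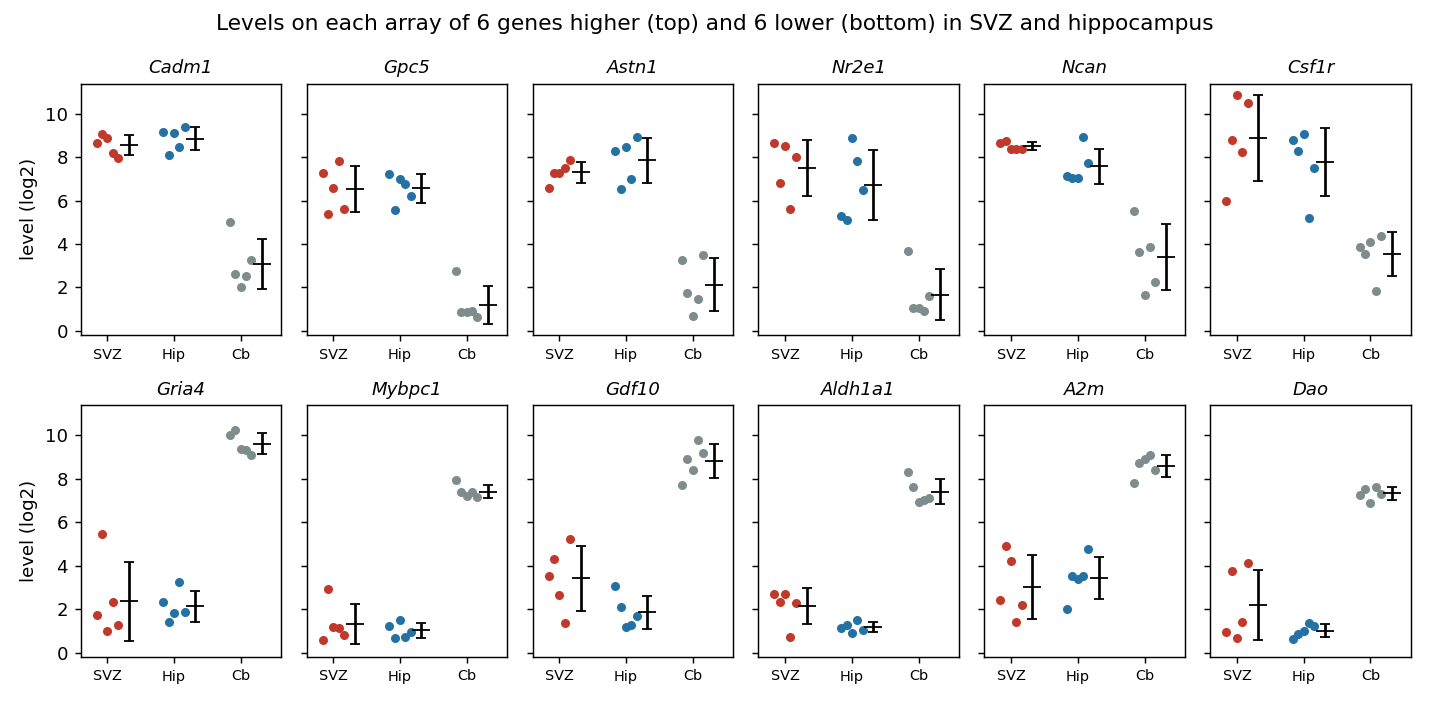
Level on each array (log2, y axis) of 6 genes higher (top) and 6 genes lower (bottom) in SVZ and hippocampus than in cerebellum (Cb), with points for the 5 arrays of each region and bars for mean ± SD. Cadm1 averages 8.54 in SVZ and 8.85 in hippocampus against 3.08 in cerebellum, while Gria4 averages 2.36 and 2.14 against 9.62.

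In all, 188 genes were higher and 814 lower in SVZ among 18194 tested. The share of probe sets above a level of 3 was at most 19.5% on the SVZ arrays and 19.8% on the hippocampus arrays, and at least 20.1% on the cerebellum arrays. Of all 18194 genes, called or not, 1568 had no overlap between the 5 and 5 arrays, an arrangement that chance gives for 0.794% of genes. The list of Bergmann glia and cerebellar astrocyte genes was lower as a group (camera adjusted p = 4.31e-12, and adjusted p = 0.0294 with an estimated correlation). Of its 19 measured members 11 were lower, 0 higher and 8 did not pass, and the count adjusted over the list alone was also 11. Besides Gria4, A2m and Gdf10, these included Hopx, a homeodomain cofactor (-5.15 ± 0.60, adjusted p = 0.000160), and Septin4, a cytoskeletal GTPase gene chosen here after its values were seen (-4.89 ± 0.56, adjusted p = 0.000139). Transcription factors of the forebrain were higher as a group (camera adjusted p = 0.00205, and adjusted p = 0.0639 with an estimated correlation). Only 3 of 31 passed, also when adjusted over the list alone, and these were Nr2e1, Lhx2 (2.71 ± 0.56, adjusted p = 0.0115) and Emx2 (2.00 ± 0.31, adjusted p = 0.00157, chosen after its values were seen). Transcription factors of midbrain and hindbrain did not pass as a group (camera adjusted p = 0.195), but did so downward with dim probe sets left out (0.000345), quantile normalization (0.0197) and the spike-in covariate (0.0128), with a mean of -0.58 and a test pointing down but a median of 0.040. Of 29 measured members, 7 were lower (9 adjusted over the list alone), among them Pax3 (-3.70 ± 0.25, adjusted p = 8.57e-07), and 22 did not pass.

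Genes of neural stem cells and radial glia went both ways in SVZ. Of 29 measured members, 5 were higher, 6 lower and 18 did not pass, or 7 higher and 8 lower adjusted over the list alone, and the group did not pass (camera adjusted p = 0.939, with a mean of -0.068 against a median of 0.24 and a test pointing up). Prom1, which encodes prominin, was higher at 3.55 ± 0.77 (adjusted p = 0.0149). Vim, the vimentin gene, was lower at -3.61 ± 0.74 (adjusted p = 0.0112). Transit amplifying cell and neuroblast genes were higher as a group (camera adjusted p = 0.0321, and adjusted p = 0.183 with an estimated correlation). Only Meis2 (3.12 ± 0.56, adjusted p = 0.00483) and Sox4 (1.51 ± 0.41, adjusted p = 0.0455) of 26 passed, or 3 adjusted over the list alone. Without cerebellum 4 the adjusted p of that list was 0.0646, and Sox4 reached an adjusted p of 0.103 without cerebellum 2, 0.0558 with quantile normalization and 0.0639 with median centring. Cell cycle genes were higher as a group (camera adjusted p = 0.000777, and adjusted p = 0.219 with an estimated correlation). Of 41 measured, Mki67, the cyclin gene Ccnd2 (2.98 ± 0.66, adjusted p = 0.0161) and the kinesin gene Cenpe passed, and 4 did adjusted over the list alone. Ccnd2 stood at 1.56 with the mean of its probe sets (adjusted p = 0.183). Cenpe, chosen after its values were seen, differed by 0.70 ± 0.18 (adjusted p = 0.0398, and 0.0966 without cerebellum 5). The Cenpe adjusted p was 0.135 with quantile normalization, 0.0810 with median centring, 0.0718 with the mean of its probe sets and 0.0639 with dim probe sets left out.

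Signalling genes differed member by member. The Notch list was higher as a group (camera adjusted p = 0.00201, and adjusted p = 0.0345 with an estimated correlation), led by Nrarp, a feedback regulator of Notch (3.82 ± 0.41, adjusted p = 7.32e-05), and the ligand gene Dner (2.97 ± 0.43, adjusted p = 0.000892). The other 22 of 24 did not pass, and the count adjusted over the list alone was also 2. In the BMP list 4 of 27 genes were lower and 1 higher (7 and 2 adjusted over the list alone, camera adjusted p = 0.195). Bmp5 stood at -3.56 ± 0.48 (adjusted p = 0.000495) and Id3, a target of BMP signals, at 2.42 ± 0.33 (adjusted p = 0.000655). In the Wnt list 5 of 38 were lower and 1, Fzd2, higher (9 and 2 adjusted over the list alone, camera adjusted p = 0.939), with Fzd1, another Wnt receptor gene, at -3.53 ± 0.54 (adjusted p = 0.00157). The FGF and EGF list had 1 lower gene of 28, Fgf12 (-1.65 ± 0.37, adjusted p = 0.0179), also adjusted over the list alone (camera adjusted p = 0.613). The Fgf12 difference was -1.37 with quantile normalization (adjusted p = 0.0932), -1.77 without cerebellum 4 and 5 (0.0689) and -1.90 with the spike-in covariate (0.144), and its difference was -0.79 with the mean of its probe sets. Of 27 genes for glutamate and GABA transport and receptors, 7 were higher and 5 lower (7 and 6 adjusted over the list alone, camera adjusted p = 0.2). The AMPA receptor subunit Gria2 was higher at 3.76 ± 0.39 (adjusted p = 5.15e-05), as was the GABA transporter gene Slc6a11 at 4.20 ± 0.52 (adjusted p = 0.000252). The subunit Gria1 was lower at -4.59 ± 0.95 (adjusted p = 0.0117).

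Genes of the astrocyte core list also split in SVZ, with 5 of 28 higher, 5 lower and 18 not past the threshold (6 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.254). S100b, a calcium-binding protein gene, was lower at -3.41 ± 0.42 (adjusted p = 0.000254) and the fatty acid carrier gene Fabp7 at -2.46 ± 0.22 (adjusted p = 1.64e-05). Cst3, the cystatin C gene, was higher at 1.41 ± 0.19 (adjusted p = 0.000629). Of 39 extracellular matrix genes, 4 were higher and 4 lower (6 and 7 adjusted over the list alone, camera adjusted p = 0.720). The brain proteoglycan genes Ncan (5.13 ± 0.59, adjusted p = 0.000143) and Bcan (3.89 ± 0.39, adjusted p = 4.50e-05) were higher, and Timp4, an inhibitor of matrix proteases, was lower (-2.42 ± 0.34, adjusted p = 0.000783). Of 21 potassium channel genes, 2 were higher and 4 lower (3 and 5 adjusted over the list alone, camera adjusted p = 0.798, with a test pointing down against a mean of 0.0060 and a median of 0.078), including Kcnj3 at -2.85 ± 0.21 (adjusted p = 1.70e-06). In the cholesterol and lipid list the transporter gene Abca1 alone passed, at 1.92 ± 0.37 (adjusted p = 0.00789; 1 of 23 also adjusted over the list alone; camera adjusted p = 0.122). That list passed upward with quantile normalization (9.8e-05), dim probe sets left out (0.0131), median centring (0.0454), the spike-in covariate (0.0126) and without cerebellum 4 and 5 (0.0189). Vim was the only passing gene of the 19 on the reactive astrocyte list (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.413). Immediate early and dissociation genes were higher as a group (camera adjusted p = 0.00147, and adjusted p = 0.559 with an estimated correlation), with 2 of 24 higher, 1 lower and 21 not past the threshold (3 and 1 adjusted over the list alone), including Nr4a2 at 3.58 ± 0.70 (adjusted p = 0.00811).

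Markers of other cell types were measured in the same sorted pools. The microglia list was higher in SVZ (camera adjusted p = 8.37e-08, and adjusted p = 0.143 with an estimated correlation), with 5 of 18 members past the threshold and 14 adjusted over the list alone. Csf1r, the receptor that sustains microglia, was 40.5-fold higher at 5.34 ± 0.92 (adjusted p = 0.00340), and Laptm5, a lysosomal gene of immune cells, was 30.2-fold higher at 4.92 ± 0.85 (adjusted p = 0.00345). These were 3.24 and 1.68 with the mean of probe sets. The others, chosen after their values were seen, were C1qa (3.46 ± 0.72, adjusted p = 0.0116), Ctss (adjusted p = 0.0281, and 0.0715 without cerebellum 4) and Fcrls (adjusted p = 0.0253, and 0.0633 without cerebellum 5). The endothelial and pericyte list was higher (camera adjusted p = 0.00592, and adjusted p = 0.538 with an estimated correlation). By either adjustment 2 of 21 passed, Pdgfrb (2.88 ± 0.62, adjusted p = 0.0145) and the glucose transporter gene Slc2a1 (1.80 ± 0.37, adjusted p = 0.0108). The adjusted p of this list was 0.0883 without SVZ 2. The oligodendrocyte precursor list was higher (camera adjusted p = 0.0223, and adjusted p = 0.370 with an estimated correlation). Olig1 (4.52 ± 0.28, adjusted p = 5.11e-07) and Olig2 (1.03 ± 0.23, adjusted p = 0.0158), transcription factors of that lineage, passed out of 13, or 3 higher and 2 lower adjusted over the list alone. The adjusted p of the precursor list was 0.0906 without SVZ 4 and 0.0511 without cerebellum 3. The oligodendrocyte list had 2 of 19 higher and 2 lower (4 and 2 adjusted over the list alone, camera adjusted p = 0.142). The connexin gene Gjc3 stood at -4.01 ± 0.50 (adjusted p = 0.000254). The choroid plexus list was lower (camera adjusted p = 0.0142, and adjusted p = 0.615 with an estimated correlation), but 0 of 12 members passed by either adjustment, and its adjusted p was 0.138 without cerebellum 5. Its mean of -1.97 became -0.93 without cerebellum 4 and 5 (adjusted p = 0.256) and turned to 0.15 with the spike-in covariate (0.709), and its adjusted p was 0.0765 with dim probe sets left out. Among cerebellar neuron markers 4 of 17 were lower, also adjusted over the list alone (camera adjusted p = 0.152, but 0.0377 without cerebellum 4, 0.0345 with quantile normalization, 2.39e-05 with the spike-in covariate and 0.00412 without cerebellum 4 and 5). The parvalbumin gene Pvalb stood at -4.11 ± 0.46 (adjusted p = 0.000115). General neuron markers had 1 lower gene of 23 by either adjustment, Syp (-2.16 ± 0.51, adjusted p = 0.0249, 0.0696 without cerebellum 2 and 0.0797 with quantile normalization; list camera adjusted p = 0.613). No member passed by either adjustment among 14 hippocampal neuron (camera adjusted p = 0.330), 12 striatal neuron (0.201), 23 ependymal (0.592) or 3 red blood cell markers (0.370).

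limma called these differences at an adjusted p under 0.05, and at an unadjusted p under 0.05 there were 3847 genes. With the spike-in level of each array as a covariate, a setting chosen after seeing the data, 40 genes were higher and 144 lower, 177 of them among the 1002. Of the 96 calls followed across settings 48 ended, while 3 of the 96 shrank by over 1.5 times and the standard errors of called genes widened by a median of 1.40 times. Calls that ended included Gria1 at -4.60 (adjusted p = 0.193), Csf1r at 5.12 (0.111), Nr2e1 at 4.68 (0.0608), Slc38a1 at -4.40 (0.0852), Laptm5 at 3.77 (0.194), Prom1 at 2.72 (0.393), Vim at -2.62 (0.373) and Dner at 1.91 (0.0639). Quantile normalization gave 213 higher and 396 lower, which lowered the share of lower genes from 81.2% to 65.0%. With the mean of a gene's probe sets, 25 of the 96 shrank by over 1.5 times and 21 of these 25 still passed, among them Fzd2 (2.54), Slc6a11 (2.16), Miat (3.38), Meis2 (1.67), Nr4a2 (1.47), Bmp5 (-1.98), Kcnj3 (-1.74), Abca1 (1.15), Syp (-0.97) and Sox4 (0.47). Without cerebellum 4 and 5, a setting also chosen after seeing the data, 30 of the 96 ended with fewer arrays, although 0 shrank by over 1.5 times. These included Prom1 at 3.25 (adjusted p = 0.121), Olig2 at 1.00 (0.113), Lhx2 at 2.53 (0.0992), C1qa at 3.28 (0.0952), Vim at -3.56 (0.0810), Nr4a2 at 3.59 (0.0614), Gria1 at -4.87 (0.0608) and Slc2a1 at 1.92 (0.0574). The counts of higher genes were 114, 119, 114 and 108 without cerebellum 2, 3, 4 and 5, with 504 lower without cerebellum 5.

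**Figure D3:**
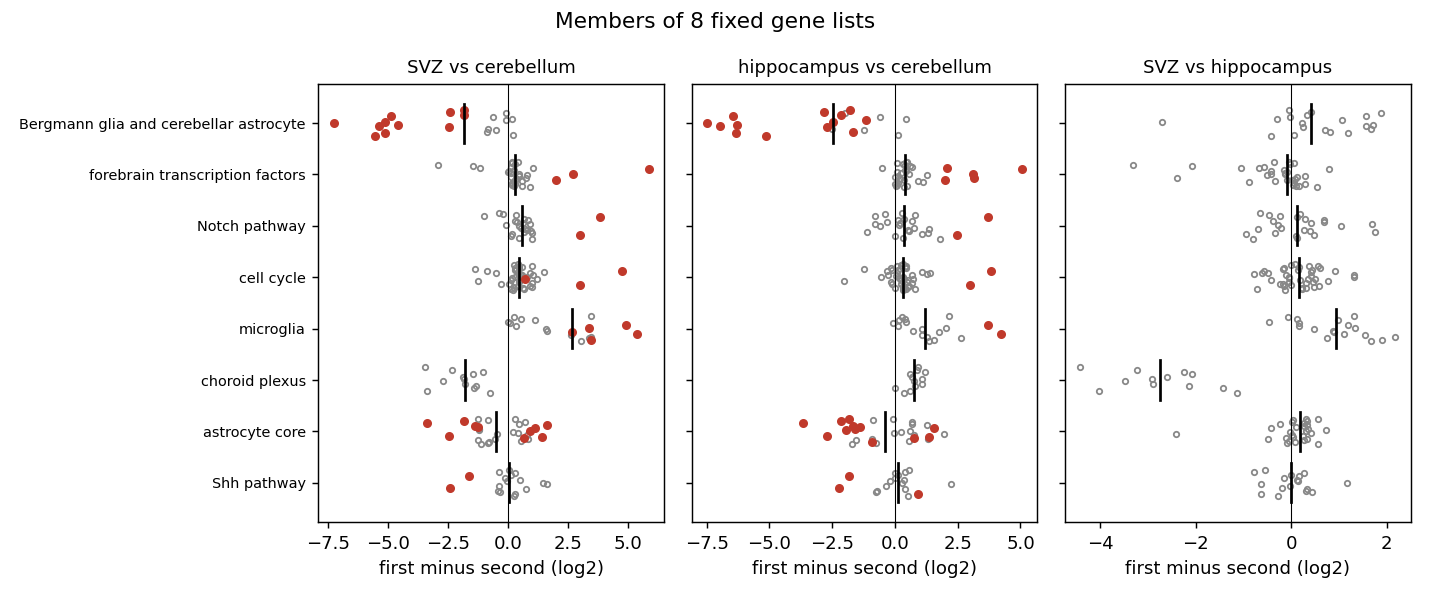
Log2 difference (x axis) of each measured member of 8 fixed gene lists in the 3 comparisons, with filled points for genes past the threshold and a black bar at the list's median. The median of the Bergmann glia and cerebellar astrocyte list lies at -1.86 for SVZ and -2.45 for hippocampus against cerebellum, and that of the microglia list at 2.64 and 1.19.

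Hippocampal astroglia were set against cerebellar astroglia in the same way, as the other region with adult stem cells. Cadm1 was higher at 54.6-fold (5.77 ± 0.47, adjusted p = 4.53e-06), as were Astn1 at 52.6-fold (5.72 ± 0.57, adjusted p = 3.34e-05), Gpc5 (5.36 ± 0.52, adjusted p = 2.63e-05) and Nr2e1 (5.05 ± 0.81, adjusted p = 0.00207). The sulfotransferase gene Chst1 was higher too (4.52 ± 0.71, adjusted p = 0.00183). Further higher genes were Fzd2 (4.40 ± 0.42, adjusted p = 1.97e-05), Rapgef3, an exchange factor activated by cAMP (4.32 ± 0.49, adjusted p = 0.000102), and the hyaluronan link protein gene Hapln1 (4.22 ± 0.60, adjusted p = 0.000744). Gria4 (-7.48 ± 0.69, adjusted p = 1.35e-05), Gdf10 (-6.95 ± 0.63, adjusted p = 1.27e-05) and Septin4 (-6.46 ± 0.56, adjusted p = 8.62e-06) were lower. Also lower were Mybpc1 (-6.40 ± 0.37, adjusted p = 1.64e-07), Dao, the D-amino acid oxidase gene (-6.32 ± 0.57, adjusted p = 1.20e-05), Gria1 (-6.31 ± 0.95, adjusted p = 0.00122), and the retinaldehyde dehydrogenase gene Aldh1a1 (-6.24 ± 0.36, adjusted p = 1.80e-07). By the same rule for naming, the 5 hippocampus arrays did not overlap the 5 cerebellum arrays for any of these genes.

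Across 18194 genes 147 were higher and 722 lower in hippocampus, and 1452 of the 18194, called or not, had no overlap between arrays, against 0.794% by chance. Bergmann glia and cerebellar astrocyte genes were lower as a group (camera adjusted p = 8.36e-17, and adjusted p = 0.0154 with an estimated correlation), with 13 of 19 lower, 6 not past the threshold and 15 lower adjusted over the list alone. Forebrain transcription factors were higher (camera adjusted p = 1.19e-05, and adjusted p = 0.0154 with an estimated correlation), with 5 of 31 members past the threshold by either adjustment, including Nr2e1 and Fezf2 (3.14 ± 0.42, adjusted p = 0.000433). Among midbrain and hindbrain factors 6 of 29 were lower and 23 did not pass (1 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.152). That list passed downward with dim probe sets left out (0.00026), quantile normalization (0.00469), the spike-in covariate (0.0128) and without cerebellum 5 (0.0481). Pax3 stood at -3.55 ± 0.25 (adjusted p = 1.17e-06). Neural stem cell and radial glia genes were split 6 higher to 6 lower of 29 (9 and 7 adjusted over the list alone, camera adjusted p = 0.928, with a median of 0.036 against a mean of -0.072 and a test pointing down). Prom1 was higher (3.74 ± 0.77, adjusted p = 0.0114) and Vim lower (-5.14 ± 0.74, adjusted p = 0.000875). No member of the 26 transit amplifying cell and neuroblast genes passed by either adjustment (camera adjusted p = 0.181). Sox11 stood at 2.71 ± 0.80 (adjusted p = 0.0740). Cell cycle genes were higher as a group (camera adjusted p = 0.0162, and adjusted p = 0.384 with an estimated correlation). Of 41, Mki67 (3.83 ± 0.75, adjusted p = 0.00850) and Ccnd2 (2.99 ± 0.66, adjusted p = 0.0176) passed, or 3 adjusted over the list alone. The Ccnd2 adjusted p was 0.0519 and no longer past the threshold without cerebellum 4, and with the mean of its probe sets it stood at 1.91 (adjusted p = 0.115). Notch genes were higher (camera adjusted p = 0.0190, and adjusted p = 0.115 with an estimated correlation). Of 24, Nrarp (3.70 ± 0.41, adjusted p = 8.73e-05) and Dner (2.49 ± 0.43, adjusted p = 0.00340) passed, or 5 adjusted over the list alone. Without hippocampus 2 the adjusted p was 0.0801 for the cell cycle list and 0.0801 for the Notch list.

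Other signalling and metabolic groups did not pass as a whole in hippocampus. The BMP list had 5 of 27 lower and 1 higher (8 and 3 adjusted over the list alone, camera adjusted p = 0.119, with a median of 0.0080 against a mean of -0.62 and a test pointing down). Bmp5 stood at -2.95 ± 0.48 (adjusted p = 0.00215). In the Wnt list 6 of 38 were lower and Fzd2 was higher (8 and 1 adjusted over the list alone, camera adjusted p = 0.764, with a median of 0.15 against a mean of -0.14 and a test pointing down). Fzd1 stood at -3.87 ± 0.54 (adjusted p = 0.000704). Of 28 FGF and EGF genes 3 were lower (5 adjusted over the list alone, camera adjusted p = 0.374). The receptor gene Fgfr2 stood at -2.41 ± 0.52 (adjusted p = 0.0148). For glutamate and GABA genes 3 of 27 were higher and 5 lower (6 and 7 adjusted over the list alone, camera adjusted p = 0.842, with a mean of -0.35 against a median of 0.34 and a test pointing up). Gria2 was higher at 3.78 ± 0.39 (adjusted p = 4.00e-05). The astrocyte core list had 3 of 28 higher and 9 lower (7 and 12 adjusted over the list alone, camera adjusted p = 0.153, and 0.0271 without hippocampus 1). Mfge8 stood at 1.54 ± 0.25 (adjusted p = 0.00233), S100b at -3.67 ± 0.42 (adjusted p = 0.000118) and Fabp7 at -2.70 ± 0.22 (adjusted p = 4.71e-06). Of 39 matrix genes 5 were higher and 7 lower (7 and 8 adjusted over the list alone, camera adjusted p = 0.453). Ncan stood at 4.20 ± 0.59 (adjusted p = 0.000727) and the proteoglycan gene Vcan at -4.09 ± 0.83 (adjusted p = 0.0109). Potassium channel genes had 1 of 21 higher and 3 lower (3 and 5 adjusted over the list alone, camera adjusted p = 0.842, with a test pointing down against a mean of 0.042 and a median of 0.014). Kcnj3 stood at -3.16 ± 0.21 (adjusted p = 4.93e-07). In the cholesterol and lipid list the desaturase gene Scd2 alone was lower, at -1.58 ± 0.33 (adjusted p = 0.0116; 1 of 23 also adjusted over the list alone; camera adjusted p = 0.323, but 0.000525 upward with quantile normalization and 0.0354 with dim probe sets left out). Of 19 reactive astrocyte genes Vim and S100a10 (-4.35 ± 1.10, adjusted p = 0.0365, 0.0898 without hippocampus 3 and 0.0681 with quantile normalization) were lower (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.667, with a mean of -0.12 against a median of 0.33 and a test pointing up). No gene of 24 on the immediate early list passed by either adjustment (camera adjusted p = 0.323, but 0.0354 with dim probe sets left out, 0.0282 with quantile normalization and 0.000175 with the spike-in covariate). Nr4a2 had 2.57 ± 0.70 (adjusted p = 0.0515).

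Of the other cell types, the microglia list was higher in hippocampus too (camera adjusted p = 0.00104, and adjusted p = 0.384 with an estimated correlation). Csf1r (4.23 ± 0.92, adjusted p = 0.0162) and Laptm5 (3.72 ± 0.85, adjusted p = 0.0212, and 0.0569 without cerebellum 2) were its 2 passing members of 18, also adjusted over the list alone. With the mean of their probe sets neither passed, at 2.36 (adjusted p = 0.0556) for Csf1r and 1.06 (adjusted p = 0.0731) for Laptm5. Endothelial and pericyte genes were higher (camera adjusted p = 0.0487, and adjusted p = 0.580 with an estimated correlation) with 1 of 21 past the threshold by either adjustment, Slc2a1 (1.66 ± 0.37, adjusted p = 0.0185, and 0.0936 with the mean of its probe sets). For the endothelial and pericyte list the adjusted p was 0.487 without hippocampus 2 and between 0.0505 and 0.0719 without SVZ 1, SVZ 3, hippocampus 5, cerebellum 2 or cerebellum 4. Oligodendrocyte genes had 1 of 19 higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.254). Olig1 stood at 4.02 ± 0.28 (adjusted p = 1.23e-06) and Gjc3 at -4.77 ± 0.50 (adjusted p = 4.60e-05). The precursor list had 1 of 13 higher and 2 lower (3 and 2 adjusted over the list alone, camera adjusted p = 0.210). Cerebellar neuron markers had 3 of 17 lower (1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0706). Pvalb stood at -4.37 ± 0.46 (adjusted p = 5.30e-05). The list's adjusted p was 0.0283, 0.0129 and 0.0235 without hippocampus 3, cerebellum 4 and cerebellum 5, and 0.00606 with quantile normalization and 1.05e-05 with the spike-in covariate. No member passed by either adjustment among 23 general neuron (camera adjusted p = 0.743), 14 hippocampal neuron (0.213), 12 striatal neuron (0.122) or 3 red blood cell markers (0.563). The same held for 23 ependymal markers (camera adjusted p = 0.563, upward) and 12 choroid plexus markers (0.356, upward). These passed without cerebellum 5 (0.0432 and 0.0123) and with the spike-in covariate (0.00191 and 1.38e-05), the choroid plexus list also without cerebellum 4 and 5 (0.0053), and both turned without hippocampus 2 (0.89 each).

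At an unadjusted p under 0.05, limma gave 3658 genes for hippocampus against cerebellum. With the spike-in level as a covariate 34 genes were higher and 178 lower, 207 of them among the 869. Of the 79 calls followed across settings 38 ended, while 3 of the 79 shrank by over 1.5 times and the standard errors of called genes widened by a median of 1.37 times. Calls that ended included Nr2e1 at 3.93 (adjusted p = 0.121), Chst1 at 3.38 (0.117), Csf1r at 4.02 (0.236), Laptm5 at 2.62 (0.437), Ncan at 3.42 (0.0537), Mki67 at 4.36 (0.0717), Vim at -4.19 (0.0639) and Prom1 at 2.95 (0.307). Quantile normalization gave 155 higher and 337 lower, a share of lower genes of 68.5% in place of 83.1%. With the mean of a gene's probe sets, 21 of the 79 shrank by over 1.5 times and 15 of these 21 still passed, among them Fzd2 (2.64), Rapgef3 (2.34), Vcan (-1.12), Bmp5 (-1.73), Kcnj3 (-1.81), Fgfr2 (-1.53) and S100a10 (-2.63). Without cerebellum 4 and 5, 24 of the 79 ended with fewer arrays, although 0 shrank by over 1.5 times. These included S100a10 at -4.46 (adjusted p = 0.166), Laptm5 at 3.07 (0.143), Fgfr2 at -2.15 (0.130), Prom1 at 3.44 (0.108), Csf1r at 3.94 (0.105), Scd2 at -1.26 (0.0974), Slc2a1 at 1.77 (0.0861), Vcan at -4.11 (0.0776) and Mki67 at 3.77 (0.0679). Single arrays moved the counts of higher genes to 228 (without hippocampus 2), 76, 84 and 92 (without cerebellum 2, 4 and 5) and those of lower genes to 469, 465 and 456 (without cerebellum 2, 4 and 5).

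Few single genes passed the threshold between SVZ and hippocampal astroglia. SVZ astroglia were 4.88-fold higher for Them4, a thioesterase gene (2.29 ± 0.30, adjusted p = 0.0216). They were 4.39-fold higher for Gsdme, the gasdermin E gene (2.13 ± 0.31, adjusted p = 0.0295), and 3.06-fold higher for Rab34, a small GTPase involved in forming cilia (1.61 ± 0.23, adjusted p = 0.0295). The noncoding RNA Kantr was lower in SVZ (-1.66 ± 0.18, adjusted p = 0.00335). For each of these 4 genes the 5 SVZ arrays and the 5 hippocampus arrays did not overlap. The same was so for 148 of all 18194 genes, about the share of 0.794% that chance gives. At an unadjusted p under 0.05 limma gave 1277 genes. At an adjusted p under 0.05, 0 genes passed in either direction with a trended and robust spread, with the mean of a gene's probe sets or with only the arrays of both regions in the fit. Them4 stood at 1.05, Gsdme at 1.08, Rab34 at 0.88 and Kantr at -0.64 with the mean of probe sets. Leaving out 1 array ended the call of Gsdme (adjusted p up to 0.125 without hippocampus 3), Rab34 (up to 0.125 without hippocampus 3) and Them4 (up to 0.0818 without hippocampus 5), while Kantr passed in all 15 such fits. The count of higher genes ran from 0 (without SVZ 4, hippocampus 5, cerebellum 3 or cerebellum 5) to 9 (without SVZ 1), and was 1 without SVZ 2, SVZ 3, hippocampus 3 or cerebellum 1, 2 or 4. That of lower genes was 2 without SVZ 1 or hippocampus 4 and 3 without hippocampus 2.

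Between SVZ and hippocampus 6 lists shifted as a group, although no list member passed the adjustment over all genes. The choroid plexus list was lower in SVZ (camera adjusted p = 1e-07, and adjusted p = 0.384 with an estimated correlation). Adjusted over the list alone 2 of 12 passed, Ttr, the transthyretin gene (-4.42 ± 1.25, adjusted p over all genes = 0.451), and Calml4 (-4.03 ± 1.23, 0.478). Microglia genes were higher in SVZ as a group (camera adjusted p = 0.00120, and adjusted p = 0.384 with an estimated correlation), with 0 of 18 past the threshold by either adjustment and the complement gene C1qa at 1.90 ± 0.72 (adjusted p = 0.590). Immediate early genes were higher as a group (camera adjusted p = 0.00157, and adjusted p = 0.559 with an estimated correlation), with 0 of 24 by either adjustment and Nr4a1 at 2.25 ± 0.68 (adjusted p = 0.478). Bergmann glia and cerebellar astrocyte genes were higher as a group (camera adjusted p = 0.00800, and adjusted p = 0.384 with an estimated correlation), with Itih3 (1.06 ± 0.30) higher and Hopx (-2.70 ± 0.60) lower adjusted over the list alone. The Bergmann glia list's adjusted p was 0.152 without SVZ 2 and 0.123 without hippocampus 2. FGF and EGF genes were higher (camera adjusted p = 0.0142, and adjusted p = 0.183 with an estimated correlation), with 1 of 28, the growth factor gene Fgf1 (1.71 ± 0.38), past the threshold adjusted over the list alone. The list's adjusted p was 0.0801 without hippocampus 2 and 0.0530 without SVZ 4. Glutamate and GABA genes were higher (camera adjusted p = 0.0170, and adjusted p = 0.384 with an estimated correlation) with 0 of 27 by either adjustment. Their adjusted p was 0.284 without hippocampus 2 and 0.0559, 0.0648 and 0.0622 without SVZ 1, 2 and 3. Among the lists that did not pass, Gfap was the 1 lower gene adjusted over the list alone both of 28 astrocyte core genes (camera adjusted p = 0.323, 0.0239 without hippocampus 1, turned at 0.707 without hippocampus 2) and of 19 reactive astrocyte genes (0.422). Hopx was that of 29 neural stem cell genes (0.655) and Fezf2 that of 31 forebrain factors (0.111, and 0.0273 without SVZ 5). Adjusted in the same way, 1 gene was higher on the BMP list (Bmpr1a of 27, camera adjusted p = 0.422), the Wnt list (Fzd5 of 38, 0.426), the matrix list (Sparc of 39, 0.882), the hippocampal neuron list (Wfs1 of 14, 0.667) and the oligodendrocyte list (Cnp of 19, 0.210).

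No member passed by either adjustment in the remaining lists of this comparison. Their camera adjusted p values were 0.949 for the Shh pathway, 0.949 for midbrain and hindbrain factors, 0.229 for transit amplifying cell and neuroblast genes, 0.426 for Notch, 0.962 for potassium channels, and 0.323 for cholesterol and lipid genes. For neurons they were 0.764 for general neurons, 0.701 for cerebellar neurons and 0.798 for striatal neurons, and for red blood cells 0.723. Cell cycle genes had 0.195 (0.0489 without SVZ 1) and endothelial and pericyte genes 0.310 (0.00771 without hippocampus 2, turned at 0.841 without SVZ 2). Ependymal genes had 0.0850 (0.0239, 0.0171 and 0.0348 without hippocampus 1, hippocampus 3 and cerebellum 5) and oligodendrocyte precursor genes 0.0620 (0.0343, 0.0471, 0.0153 and 0.0481 without SVZ 2, SVZ 5, hippocampus 5 and cerebellum 5). Mean, median and test differed in sign for the Shh list (mean -0.018, median 0.0020, test up) and midbrain and hindbrain factors (mean -0.072, median 0.036, test down). They also did for potassium channels (mean -0.036, median 0.064, test up), matrix genes (mean 0.085, median -0.0020, test up) and cerebellar neurons (mean -0.045, median 0.088, test up).

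The design then asked which genes both stem cell regions share against cerebellum, at more than 4-fold and an unadjusted p under 0.01. SVZ alone had 120 higher and 464 lower genes at these thresholds and hippocampus 77 and 445. Of these, 54 were higher and 254 lower in both, with 0 in opposite directions. Of the common higher genes, Cadm1 (5.46 in SVZ and 5.77 in hippocampus), Gpc5 (5.32 and 5.36), Astn1 (5.17 and 5.72), Nr2e1 (5.85 and 5.05) and Chst1 (4.51 and 4.52) had the largest smaller difference. They were followed by Fzd2, Rapgef3, Csf1r, Ncan and Olig1, the last at 4.52 and 4.02. Gria4 (-7.26 and -7.48), Mybpc1 (-6.10 and -6.40), Slc38a1 (-5.90 and -5.81), Gdf10 (-5.40 and -6.95) and Cnpy1 (-5.30 and -5.42) led the common lower genes. They were followed by Aldh1a1, Frrs1l, the AMPA receptor auxiliary subunit gene Cacng5, A2m and Dao. Within these 308 genes the median absolute difference between SVZ and hippocampus was 0.36. Them4 and Gsdme were the 2 that differed between SVZ and hippocampus at an adjusted p under 0.05, by adjustment over all genes or over the 308 alone, the latter not independent evidence because the list came from the same arrays. At an unadjusted p under 0.05 there were 22, where 15.4 would be expected by chance. The count of 2 became 1 without SVZ 5 or cerebellum 4 and 5 without SVZ 4.

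Both comparisons used the same 5 cerebellum arrays, which alone makes them alike. Independent lists of these sizes would share 0.508 higher and 11.3 lower genes. In 100 simulations of unchanged regions on the shared arrays the means were 0.24 and 0.26. Other splits of the real arrays gave up to 40 and 38. Their mixed groups still held real differences between the regions, so these counts cannot show what shared arrays alone give. The simulations drew each gene independently and may understate how far overlap, r and covariance vary by chance. With the cerebellum arrays split between both comparisons in 20 ways, 35 to 49 genes were higher and 174 to 198 lower in both. Across genes, which are not independent replicates, the SVZ and hippocampus differences correlated with Pearson's r of 0.783 and Spearman's rho of 0.687, against a simulated r of 0.249 with no effect and a mean r of 0.673 with the split arrays. The covariance was 0.539 against 0.0451 in the simulations, a difference of 0.494. Quantile normalization lowered the common lower genes to 139, and the mean of a gene's probe sets gave 34 common higher and 165 common lower genes.

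**Figure D4:**
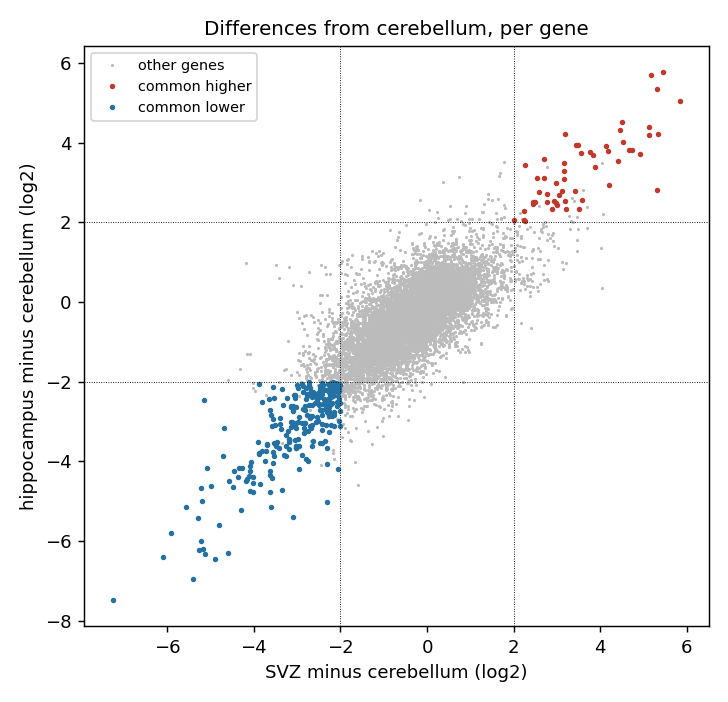
Log2 difference from cerebellum of each of 18194 genes in SVZ (x axis) and hippocampus (y axis), with dotted lines at 4-fold and colours for the 54 common higher and 254 common lower genes. Both axes share the same 5 cerebellum arrays, and no gene passes the thresholds in opposite directions.

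Genes at a high level in both stem cell regions were taken as those in the top 10% by mean level in each, 1820 per region. The regions shared 1521 (1304 also with cerebellum), against 1408 for SVZ and 1456 for hippocampus with cerebellum. The cutoffs were 4.91 in SVZ and hippocampus and 5.73 in cerebellum. Of the 28 astrocyte core genes measured, 26 were at a high level in both regions. In both regions 57 of the 1521 genes were also higher than in cerebellum at an adjusted p under 0.05, led by the same 10 genes as the common higher genes. Cadm1 stood at 8.54 ± 0.46 in SVZ, 8.85 ± 0.54 in hippocampus and 3.08 ± 1.16 in cerebellum (mean ± SD, n = 5). Rapgef3 stood at 9.26 ± 0.57, 9.13 ± 0.49 and 4.82 ± 1.21, and Ncan at 8.51 ± 0.18, 7.58 ± 0.80 and 3.38 ± 1.52.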

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

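The tests of the spike-in level over genes picked by fold alone, of varying amounts of microglial or choroid plexus RNA, and of single arrays for choroid plexus were chosen only after the result was seen, and the other tests were written before. A sample stood far from the other 4 of its region, by the ratio of its gap to the range, in 33 of 411 groups of values, a share of 8.03% where chance gives about 1 in 20. These were 133 genes and 4 measures of each array in each region, the measures being the spike-in level, the share of probe sets above a level of 3, and the means of the microglia and choroid plexus lists. In SVZ the ratio was 0.778 for Btg2, 0.836 for Hsp90aa1 (both low) and 0.720 for Cdon (high) in array 1, 0.735 for Irx1 and 0.746 for Mybpc1 (high) and 0.879 for the spike-in level (low) in array 2, and 0.713 for Gli1 (high) in array 3. Array 4 of SVZ was low for Aldh1a1 (0.791) and Gria1 (0.717) and high for Vcan (0.782), and array 5 was high for Gjc3 (0.730) and Pvalb (0.746) and low for Timp4 (0.725).

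In hippocampus, array 1 was high for Pcp2 (0.849), and array 2 was high for Bmpr1a (0.814), Nr4a1 (0.831) and Sox4 (0.744) and low for Egfr (0.844), Hapln1 (0.747) and Slc1a3 (0.734). Array 4 was low for Grin2c (0.813) and high for Hhip (0.802), and array 5 was high for Gli1 (0.861), at 6.22 against a mean of 1.98 in the others. In cerebellum, array 1 was high for Chst1 (0.885), Gpc5 (0.869), Nr2e1 (0.749) and Prom1 (0.787) and low for Btg2 (0.862). Array 3 was high for Fabp7 (0.750) and low for Bcan (0.712), Kcnip3 (0.746) and Smo (0.719), and array 5 was high for Thbs3 (0.734).

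The effects of SVZ and hippocampus against cerebellum differed from each other, by the direct test in limma, for Them4 (2.29), Gsdme (2.13), Rab34 (1.61) and Kantr (-1.66). Of 100 splits of these arrays, 7 gave as many genes as the real 4, with up to 10 in another split and some gene in 37, so chance is not excluded for this count. At the preset correlation 6 lists shifted between SVZ and hippocampus, with adjusted p values of 0.00800 (Bergmann glia and cerebellar astrocyte), 0.0142 (FGF and EGF), 0.0170 (glutamate and GABA), 0.00157 (immediate early), 1e-07 (choroid plexus) and 0.00120 (microglia). None of the 6 passed with an estimated correlation, where the adjusted p values in the same order were 0.384, 0.183, 0.384, 0.559, 0.384 and 0.384. Chance was excluded for SVZ against cerebellum, where 1 of 100 splits, the real one, gave 1002 genes and the highest other gave 5, and for hippocampus against cerebellum, where 1 of 100 gave 869 and the highest other 5. It was also excluded for the common genes, with 1 of 100 splits each, at 254 lower genes against 38 and 54 higher genes against 40 in the highest other split.

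In data outside the comparisons, the poly-A spike-in signal was 4.85-fold higher in SVZ and 4.52-fold higher in hippocampus than in cerebellum. The two-sided exact permutation p was 0.0159 for each, where the smallest that 252 splits can give is 0.00794. If the controls were added at a fixed amount to each pool, which the labels do not state, more spike-in signal beside the sample's own RNA may mark pools with less starting RNA, and 81.2% and 83.1% of called genes were lower than in cerebellum. With the spike-in level as a covariate, the median drop of the genes lower in SVZ went from -1.92 to -1.74, so 90.5% remained (80.9% to 94.1% when 1 array was left out), but these genes were picked for arrays that agree, and wider standard errors (1.40 and 1.37 times) ended many calls. Over the 2523 genes lower by more than 2-fold in SVZ, whatever their p, 84.7% of the drop remained (68.3% without cerebellum 1). The share of lower genes was 78.3% in SVZ and 84.0% in hippocampus among genes called with the covariate, but fell from 79.0% to 65.6% and from 83.6% to 68.3% among all genes over 2-fold, so starting RNA stays open. Scaling stays open too, since the share of lower genes was 65.0% in SVZ and 68.5% in hippocampus under quantile normalization but 87.7% and 89.6% under median centring, and so does a difference between the regions themselves, which was not tested.

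The microglia markers Csf1r and Laptm5 were higher in both stem cell regions, although the sort for the red and green reporters would exclude microglia. Their list, with 5 of 18 members past the threshold in SVZ and 2 in hippocampus, did not pass with an estimated correlation (adjusted p = 0.143 and 0.384). Without these 2 genes the median of the other 16 was 2.11 in SVZ (1.71 to 2.52) and 1.08 in hippocampus, and 2 of 5 abundant microglial genes passed, so microglia among the sorted cells may explain the pattern and remain open. A change that lifts the markers of every other cell type alike is argued against, since in SVZ the microglia list median lay above those of the endothelial, oligodendrocyte and general neuron lists by 2.05, 2.46 and 2.70, and in hippocampus by 0.611, 0.949 and 1.19 (the second gap was at least 0.555 when 1 array was left out). Within regions the members' mean pairwise correlation of 0.215 exceeded that of 100% of 10000 matched random lists (95th percentile 0.0590). The astrocyte core list had 0.303, so this cannot single out varying microglial RNA. No measured member of this list stands on another list. Expression in the astroglia of these regions was not tested and stays open.

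The choroid plexus list had a mean difference, SVZ minus hippocampus, of -2.72, although the same sort would exclude choroid cells. It did not pass with an estimated correlation (adjusted p = 0.384), and 0 of its 12 members passed over all genes. Within regions the members' mean pairwise correlation of 0.786 exceeded that of 100% of 10000 matched random lists (95th percentile 0.110). Random lists hold unrelated genes, so varying choroid plexus RNA stays open but is not singled out. Of its 12 measured members 1, Otx2, also stands on the forebrain list. Ttr ranged from 5.96 to 10.35 in SVZ and from 11.18 to 13.94 in hippocampus. Without hippocampus 2, 69.7% of the difference remained, and without hippocampus 5, 84.7%. The drop without hippocampus 2 was too large to exclude a single array as the source and too small to show one, so this stays open. Both arrays were not left out together. Their list means stood apart at 7.87 and 6.24, against 2.17 to 3.43 in the other hippocampus and 1.48 to 2.15 in the SVZ arrays. No biological explanation was tested.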

How the results depend on the processing

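The settings that left out SVZ 1 with hippocampus 3, left out cerebellum 4 with cerebellum 5, or used the spike-in level as a covariate were chosen only after the result was seen, and the others were planned. The values below are camera adjusted p values for lists and log2 differences for genes, the cause of each change was not tested unless named, and a list said to have turned passed in neither direction unless stated. For the 22 lists that passed, 498 of 550 values under all settings kept direction and threshold, 51 lost the threshold and 1 turned, and for the 65 others 1488 of 1622 values did not change side, 62 passed and 72 turned. For the 179 named calls, 3949 of 4474 values kept the call, 525 lost it and 0 turned, and for 48 named values that did not pass 30 of 1200 passed and 31 turned. The signal of dim genes lies near the background of the arrays and limits what can be told of them.

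Pairing of the arrays by equal replicate numbers was not shown: deviations of arrays with the same number correlated from -0.12 to 0.138, above 0.1 in 3 of 15 pairs. Some values hinted at it, since 7 of 15 arrays correlated best with their own number, and each SVZ array correlated best among the cerebellum arrays with that of its own number (0.027 to 0.111). With the replicate block 1011 genes were called in SVZ-cerebellum (852 of the 1002 among them) and 814 in hippocampus-cerebellum (692 of the 869), and all 4 of SVZ-hippocampus were kept. The block moved neuroblast genes in SVZ-cerebellum to 0.0636 and turned potassium channels in SVZ-hippocampus (0.97). It ended 6 of 96 named calls in SVZ-cerebellum, among them Sox4 (adjusted p = 0.0634) and Cenpe (0.0627), and 6 of 79 in hippocampus-cerebellum, among them Cdon (0.0552).

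An adjusted in place of the unadjusted p under 0.01, at over 4-fold, gave 54 higher and 211 lower genes in SVZ-cerebellum. It gave 36 and 232 in hippocampus-cerebellum, and 29 common higher and 142 common lower genes. Array weights gave 409 higher genes in SVZ-cerebellum and 244 in hippocampus-cerebellum. It turned the difference of Smo (-0.0089) in hippocampus-cerebellum. Leaving out dim probe sets ended the shift of choroid plexus (0.0765) in SVZ-cerebellum. It added a shift of cholesterol (0.0131), hindbrain factors (0.000345) and oligodendrocyte (0.0246) in SVZ-cerebellum, cholesterol (0.0354), immediate early (0.0354), hindbrain factors (0.00026), neuroblast (0.0443) and precursor (0.0198) in hippocampus-cerebellum and forebrain factors (0.0147), ependymal (0.0354) and oligodendrocyte (0.0354) in SVZ-hippocampus. It turned Wnt (0.862), neural stem cell (0.446) and potassium channels (0.588) in hippocampus-cerebellum, potassium channels (0.943) in SVZ-cerebellum and potassium channels (0.564), hippocampal neuron (0.856) and striatal neuron (0.769) in SVZ-hippocampus. A trended and robust spread gave 0 higher and 0 lower genes in SVZ-hippocampus. An estimated correlation ended the shift of Bergmann glia (0.384), FGF and EGF (0.183), glutamate and GABA (0.384), immediate early (0.559), choroid plexus (0.384) and microglia (0.384) in SVZ-hippocampus, Notch (0.115), cell cycle (0.384), endothelial (0.58) and microglia (0.384) in hippocampus-cerebellum and cell cycle (0.219), forebrain factors (0.0639), immediate early (0.559), neuroblast (0.183), choroid plexus (0.615), endothelial (0.538), microglia (0.143) and precursor (0.37) in SVZ-cerebellum.

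Counting every probe set, in place of genes, gave 325 higher and 1481 lower in SVZ-cerebellum, and 213 and 876 over 4-fold. In hippocampus-cerebellum it gave 243 and 1285, and 132 and 811 over 4-fold. It gave 92 common higher and 475 common lower. The mean of probe sets per gene gave, over 4-fold, 286 lower genes in SVZ-cerebellum and 44 higher and 269 lower in hippocampus-cerebellum. It gave 34 common higher, 165 common lower and, in SVZ-hippocampus, 0 higher and 0 lower genes. It ended the shift of neuroblast (0.053) in SVZ-cerebellum and endothelial (0.0709) in hippocampus-cerebellum. It added a shift of cerebellar neuron (0.0393) and striatal neuron (0.0487) in hippocampus-cerebellum and ependymal (0.0417) and precursor (0.0459) in SVZ-hippocampus. It turned Wnt (0.987) and potassium channels (0.881) in SVZ-cerebellum, neural stem cell (0.92) and potassium channels (0.881) in hippocampus-cerebellum and potassium channels (0.987) in SVZ-hippocampus. It turned the difference of Gli2 (0.103) in SVZ-hippocampus, Hhip (-0.068) in SVZ-hippocampus, Hhip (0.0025) in hippocampus-cerebellum and Smo (0.0427) in SVZ-cerebellum. Median centring added a shift of cholesterol (0.0454) in SVZ-cerebellum and cerebellar neuron (0.0436) in hippocampus-cerebellum. It turned neural stem cell (0.79) in hippocampus-cerebellum. A fit of only the groups compared gave 0 higher and 0 lower genes in SVZ-hippocampus. A threshold of 2-fold, not 4-fold, at the unadjusted p, gave 245 higher and 1193 lower genes in SVZ-cerebellum and 157 and 1154 in hippocampus-cerebellum. It gave 96 common higher and 716 common lower genes, and 5 SVZ-hippocampus genes within them. Quantile normalization gave 396 lower genes and 253 over 4-fold in SVZ-cerebellum, 337 and 229 in hippocampus-cerebellum, and 139 common lower genes. It ended the shift of neuroblast (0.0989) in SVZ-cerebellum. It added a shift of cholesterol (9.8e-05), hindbrain factors (0.0197) and cerebellar neuron (0.0345) in SVZ-cerebellum, cholesterol (0.000525), immediate early (0.0282), hindbrain factors (0.00469) and cerebellar neuron (0.00606) in hippocampus-cerebellum and precursor (0.0308) in SVZ-hippocampus. It turned astrocyte core (0.958) in SVZ-cerebellum, hindbrain factors (0.861) in SVZ-hippocampus and neural stem cell (0.601) in hippocampus-cerebellum. It turned the difference of Gli1 (0.0563) in hippocampus-cerebellum, Hhip (0.1024) in SVZ-cerebellum and Smo (0.0124) in SVZ-cerebellum.

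The spike-in level as a covariate gave 40 higher, 144 lower and, over 4-fold, 262 lower genes in SVZ-cerebellum. It gave 34, 178 and 292 in hippocampus-cerebellum and 1 higher gene in SVZ-hippocampus. It ended the shift of neuroblast (0.0827) and precursor (0.074) in SVZ-cerebellum. It added a shift of cholesterol (0.0126), hindbrain factors (0.0128), cerebellar neuron (2.39e-05) and general neuron (0.0164) in SVZ-cerebellum, immediate early (0.000175), hindbrain factors (0.0128), cerebellar neuron (1.05e-05), choroid plexus (1.38e-05), ependymal (0.00191) and general neuron (0.0431) in hippocampus-cerebellum and precursor (0.0431) in SVZ-hippocampus. It turned glutamate and GABA (0.705), neural stem cell (0.681) and red blood cell (0.963) in hippocampus-cerebellum, potassium channels (0.957) in SVZ-hippocampus and choroid plexus (0.709) and ependymal (0.0955) in SVZ-cerebellum. It turned the difference of Gfap (0.5352) in SVZ-cerebellum and Smo (0.2382) in SVZ-cerebellum. The top 20% in place of the top 10% gave 3117 genes at a high level in both. The top 5% gave 755 genes at a high level in both. Leaving out SVZ 1 and hippocampus 3 gave 7 higher and 2 lower genes in SVZ-hippocampus and 5 SVZ-hippocampus genes within the common genes. It ended the shift of FGF and EGF (0.0557) and glutamate and GABA (0.0655) in SVZ-hippocampus. It added a shift of cerebellar neuron (0.0372) in hippocampus-cerebellum and ependymal (0.0297) in SVZ-hippocampus. It turned neural stem cell (0.959) and potassium channels (0.947) in hippocampus-cerebellum and potassium channels (0.681) in SVZ-hippocampus. It turned the difference of Gli1 (0.035) in SVZ-hippocampus and Smo (-0.093) in hippocampus-cerebellum. Leaving out cerebellum 4 and cerebellum 5 gave 71 higher and 297 lower genes in SVZ-cerebellum and 61 and 297 in hippocampus-cerebellum. It gave 0 higher genes in SVZ-hippocampus and 1 SVZ-hippocampus gene within the common genes. It ended the shift of neuroblast (0.149) and choroid plexus (0.256) in SVZ-cerebellum and endothelial (0.0871) in hippocampus-cerebellum. It added a shift of cholesterol (0.0189) and cerebellar neuron (0.00412) in SVZ-cerebellum, cerebellar neuron (0.00102) and choroid plexus (0.0053) in hippocampus-cerebellum and ependymal (0.035) in SVZ-hippocampus. It turned neural stem cell (0.702) in hippocampus-cerebellum and ependymal (0.693) in SVZ-cerebellum. It turned the difference of Gfap (0.1647) in SVZ-cerebellum and Smo (0.1773) in SVZ-cerebellum.

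Leaving out 1 array at a time gave 108 to 217 higher and 504 to 894 lower genes in SVZ-cerebellum. In hippocampus-cerebellum it gave 76 to 228 and 456 to 934. In SVZ-hippocampus it gave 0 to 9 and 1 to 3, and 1 to 5 within the common genes. In SVZ-cerebellum, lists that passed and lost it in some of these fits had adjusted p values of 0.0222 to 0.0646 (neuroblast), 0.000981 to 0.138 (choroid plexus), 0.0118 to 0.0906 (precursor) and 0.000687 to 0.0883 (endothelial). In SVZ-cerebellum, lists that passed in some only had adjusted p values of 0.0377 to 0.326 (cerebellar neuron). In SVZ-cerebellum, lists that turned without passing had adjusted p values of 0.764 to 0.976 (Shh), 0.712 to 0.995 (neural stem cell), 0.832 to 0.994 (Wnt), 0.405 to 0.976 (general neuron) and 0.301 to 0.733 (ependymal). In hippocampus-cerebellum, lists that passed and lost it in some of these fits had adjusted p values of 0.00518 to 0.0801 (cell cycle), 0.0073 to 0.0801 (Notch) and 0.0172 to 0.487 (endothelial). In hippocampus-cerebellum, lists that passed in some only had adjusted p values of 0.0271 to 0.484 (astrocyte core), 0.0481 to 0.344 (hindbrain factors), 0.0129 to 0.165 (cerebellar neuron), 0.0432 to 0.89 (ependymal, turned at 0.89 without hippocampus 2) and 0.0123 to 0.89 (choroid plexus, turned at 0.89 without hippocampus 2). In hippocampus-cerebellum, lists that turned without passing had adjusted p values of 0.715 to 0.976 (Shh), 0.739 to 0.987 (neural stem cell), 0.497 to 0.971 (glutamate and GABA), 0.669 to 0.976 (potassium channels), 0.427 to 0.911 (reactive astrocyte), 0.138 to 0.89 (immediate early) and 0.374 to 0.991 (general neuron). In SVZ-hippocampus, lists that passed and lost it in some of these fits had adjusted p values of 0.0012 to 0.152 (Bergmann glia), 0.00889 to 0.0801 (FGF and EGF) and 0.00518 to 0.284 (glutamate and GABA). In SVZ-hippocampus, lists that passed in some only had adjusted p values of 0.0239 to 0.707 (astrocyte core, turned at 0.707 without hippocampus 2), 0.0273 to 0.344 (forebrain factors), 0.0489 to 0.543 (cell cycle), 0.0171 to 0.574 (ependymal), 0.0153 to 0.161 (precursor) and 0.00771 to 0.841 (endothelial, turned at 0.841 without SVZ 2). In SVZ-hippocampus, lists that turned without passing had adjusted p values of 0.627 to 0.994 (Shh), 0.679 to 0.993 (hindbrain factors), 0.541 to 0.994 (potassium channels), 0.51 to 0.991 (matrix), 0.399 to 0.962 (general neuron) and 0.366 to 0.879 (hippocampal neuron). Differences that did not pass and turned ran from -0.3045 to 0.073 for Hhip in SVZ-cerebellum, -1.4005 to 0.3595 for Smo in SVZ-cerebellum, -0.1585 to 1.152 for Smo in hippocampus-cerebellum, -0.0335 to 0.6765 for Gli3 in hippocampus-cerebellum, -0.593 to 0.82 for Gli1 in SVZ-hippocampus, -0.0475 to 0.4745 for Ptch1 in SVZ-hippocampus and -0.1165 to 0.467 for Hhip in SVZ-hippocampus.

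The median of all genes against cerebellum was 0.068 in both regions as deposited, 0.0455 (SVZ) and 0.0555 (hippocampus) under quantile normalization, and -0.036 and -0.044 under median centring, and no list that passed turned under either scaling. With the cerebellum arrays split, the correlation of both differences was 0.673.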
